A study of Homo sapiens with 11 samples.

How the data were processed

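Total RNA from SCC9 cells was measured on 11 Affymetrix U133A arrays, which read each transcript with sets of short probes, and 1 array was used per sample. Per the labels, the authors summarised the arrays with RMA, which corrects the background, equalises the distributions of the arrays and combines the probes of each probe set. The deposited values are log2 intensities per probe set, judged from their range of 2.53 to 13.4 and from array medians between 5.37 and 5.43. The RMA version, and which arrays were normalised together, were not given in the sources used here. Quantile steps of this kind set the arrays to a common distribution, so a shift of all transcripts in one direction would not be visible in these values.

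The deposited table held 16383 probe sets with no missing value, and all of them were tested. A table pairing probe sets with genes gave 1 symbol for 14045 probe sets, several symbols for 792 and none for 1546. A gene was represented by the probe set with the highest mean over all 11 arrays among those with 1 symbol, which gave 8549 genes, of which 3362 had several probe sets. Numbers of genes refer to this representative probe set unless stated otherwise. No genome build was used, so no positions are given. The table held 0 Affymetrix control probe sets. The planned comparison of RNA quality between arrays, which needs the 3-prime and 5-prime control probe sets of GAPDH and ACTB, could therefore not be run.

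The arrays fell into 4 treatments: 3 control, 3 cisplatin, 3 nimesulide and 2 combination arrays. A combination array for replicate C was not analysed here. Without a term for the replicate letter, differences between letters can therefore enter the contrasts of the combination. A model with a mean per treatment was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), which left 7 residual degrees of freedom shared by the 4 treatments. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 16383 probe sets within each of 7 contrasts. These were cisplatin, nimesulide and the combination against control, the combination against each single agent, nimesulide against cisplatin, and the interaction (combination minus cisplatin minus nimesulide plus control). A probe set was called at an adjusted p under 0.05, and calls were also counted at a fold change of at least 2. The number of arrays limits the precision, with a median standard error of 0.08 log2 units for 3 arrays against 3. The labels speak of experiments done in triplicate and do not state outright that each array came from a separate culture, so the p-values measure the spread between these samples.

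The deposited protocol describes replicate sets A, B and C, each with RNA of all 4 treatments. It does not state outright that a letter stands for a shared culture or day. The pairing was checked by correlating the arrays after removal of each treatment's mean. Arrays with the same letter correlated at 0.135 to 0.355 (median 0.247, 6 pairs) between control and a single agent, and at 0.0831 to 0.232 (3 pairs) between cisplatin and nimesulide. Same-letter pairs with a combination array gave 0.0883 to 0.210 (6 pairs), and pairs with different letters among the other 3 treatments gave -0.251 to 0.0342 (18 pairs). Different-letter pairs with a combination array gave -0.210 to 0.144 (12 pairs), but with 2 combination arrays the values of the 1 are those of the other with the sign turned, so these 12 add nothing to the same-letter pairs. Removing treatment means makes the values between 2 treatments balance around 0, so they compare pairs with each other. A fit with the letter as a replicate block (5 residual degrees of freedom) was planned as an alternative, and its values are printed beside the results where they change a call, a number of calls or, for lists called without it, the number of members passing adjusted over the list alone. The fit without the block, as fixed beforehand, gives the reported calls.

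A total of 26 gene lists holding 838 different genes was fixed, and 684 of these genes were measured, between 9 and 47 per list. Some genes belong to several lists. Each list was tested with limma's camera on 1 probe set per gene, at the preset inter-gene correlation of 0.01, with adjustment over the 26 lists within a contrast. Camera asks whether a list's genes stand higher or lower than the other genes. The test was repeated with a correlation estimated from the arrays for each list, and that p is given beside each call. Members were counted as passing over all probe sets and adjusted over the list alone. In lists that were not called, the direction of the test, the median and the mean sometimes differed in sign; in every called list they had the same sign.

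Named genes followed a rule. For each treatment against control these were, among genes past the threshold whose arrays did not overlap between the groups, the 10 with the largest rise and the 10 with the largest fall, or all that passed where fewer did. For the combination against each single agent and for the interaction the number was 5 in each direction. Where none passed, the 5 genes with the smallest p in each direction were named and given as values. In addition, the 2 to 4 members with the smallest p of each list described were named, and CDKN1A, MDM2, GADD45A, PTGS2, PTGS1 and BIRC5 whatever their values. Genes named outside this rule are said to have been chosen after their values were seen. No named gene had probe sets called in opposite directions. The contrasts, lists, thresholds, naming rule and most alternatives were set before the data were examined.

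The calls were tested on simulated data with the same 11 arrays, in 20 simulations under each of 2 noise settings. In each, 100 of 16383 probe sets were shifted by 0.5 and another 100 by 1 log2 unit. For cisplatin against control, 73.2 to 88.5% of shifts of 0.5 were recovered (98.95 to 99.9% of shifts of 1). For nimesulide against control these shares were 74.6 to 88.9% and 98.9 to 99.8%, and for the combination against control 62.5 to 75.0% and 97.9 to 99.8%. The false share of calls was 0.476 to 1.44% without the block and 3.69 to 6.65% with it. In simulated data with independent genes, camera called the 1 shifted list (-0.3, 33 genes, nimesulide against control) and 0 of the others. These simulations held no correlation between genes. Those of the probe set calls also shifted many probe sets at once, which makes the adjusted threshold easier to pass. The recovered shares therefore do not carry over to contrasts with few or no calls, and do not exclude missed changes there. With nimesulide against control, for example, IFI44L at -1.39 had a limma adjusted p = 0.30 without the block.

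Alternatives covered the replicate block, each array left out in turn, the normalization, the moderation of the spread, array weights, dim or shared probe sets, the unit of the test, a linear pseudocount of 32, the fold threshold, and the inter-gene correlation. Gene-by-gene agreement between contrasts was measured with Pearson's r and Spearman's rho across 8549 genes, which are not independent replicates, so no p is given. For contrasts that share the controls, the covariance is given beside that of 100 simulations without any effect, with independent arrays and with the letters kept.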

Results

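Gene expression was profiled in SCC9, an established human cell line from a squamous carcinoma of the tongue. The cells received 100 µmol/L nimesulide, an anti-inflammatory drug that preferentially inhibits the prostaglandin-forming enzyme cyclooxygenase-2, or 0.5 µmol/L cisplatin, a platinum drug that crosslinks DNA, or both agents, or neither. Control, cisplatin and nimesulide each had 3 arrays, from replicates A, B and C, and the combination had 2, from replicates A and B. The log2 values of 16383 probe sets, covering 8549 genes, correlated at 0.996 to 0.998 between arrays of the same treatment (10 pairs) and at 0.995 to 0.998 between arrays of different treatments (45 pairs).

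Nimesulide against control asks what the cyclooxygenase-2 inhibitor alone does to these cells. The interferon-stimulated genes, which interferon induces and which act in antiviral defence, were lower with nimesulide. Their mean level was 7.92 ± 0.26 log2 units in controls and 7.45 ± 0.15 with nimesulide (SD, n = 3 each), and all 33 measured members had a lower mean. The mean of this list also ranged over 0.52 among the 3 controls, which is more than the difference of -0.47 between nimesulide and control. That range followed the replicate letters. Less the control mean, letters A, B and C stood at -0.26, 0.26 and 0.00 in controls. With cisplatin they stood at -0.17, 0.24 and 0.03. Within letters A, B and C the median change with nimesulide was -0.34, -0.54 and -0.49. IRF7, a transcription factor that drives type I interferon production, fell by 0.61 log2 units (SE 0.07, n = 3 each, adjusted p = 0.00727), from 8.55 ± 0.10 to 7.94 ± 0.07. Genes of the ATF4 and amino acid response, which cells induce when amino acids are scarce or the endoplasmic reticulum is stressed, were higher, at 8.23 ± 0.03 against 8.07 ± 0.04 (SD, n = 3 each).

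The interferon list fell as a group (camera, adjusted p = 5.55e-35, median log2 change -0.44). That call was lost at adjusted p = 0.167 with an estimated correlation. Of its 33 members, 1 fell over all probe sets and 24 fell adjusted over the list alone (29 with the block). Beside IRF7, the members with the smallest p were ISG15, a ubiquitin-like antiviral protein (-0.64, SE 0.11, adjusted p = 0.203), IFITM1, which blocks virus entry (-0.41, SE 0.08, adjusted p = 0.250), and IFI35 (-0.57, SE 0.12, adjusted p = 0.30). None of these 3 passed over all probe sets, but all 3 did with the replicate block, at adjusted p = 0.00310, 0.0184 and 0.00255. IFI44L had the lowest value of the list (-1.39, SE 0.29), while IRF1 and GBP2 lay nearest 0, both at -0.06.

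The ATF4 list rose as a group (camera, adjusted p = 3.60e-13, median 0.13, 28 of 32 members higher). Its adjusted p = 0.167 with an estimated correlation. None of its members passed over all probe sets, and 6 rose adjusted over the list alone. These were STC2 (0.57, SE 0.11), the serine synthesis enzyme PSPH (0.50, SE 0.09), the cystine transporter SLC7A11 (0.50, SE 0.10), asparagine synthetase ASNS (0.40, SE 0.09), CEBPG (0.37, SE 0.10) and the mitochondrial folate enzyme MTHFD2 (0.32, SE 0.07). ATF4 itself was at 0.04 and DDIT3, another stress-induced transcription factor, at -0.01.

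Genes of the G1/S transition and DNA replication fell as a group with nimesulide (adjusted p = 3.35e-09, median -0.10, 34 of 36 members lower, adjusted p = 0.498 with an estimated correlation). POLA1, the catalytic subunit of DNA polymerase alpha, was at -0.25 (SE 0.07) and CDC45, part of the replicative helicase, at -0.24 (SE 0.08), and neither passed. Immediate early genes, which respond within minutes to growth factors or stress, rose slightly as a group (adjusted p = 0.00919, median 0.05, 22 of 28 higher, adjusted p = 0.498 with an estimated correlation), with the phosphatase DUSP5 at 0.24 and the transcription factor KLF6 at 0.23. Oxidative phosphorylation genes were slightly lower (adjusted p = 0.0358, median -0.04, 32 of 47 lower) and basal keratinocyte and adhesion genes slightly higher (adjusted p = 0.0455, median 0.05, 17 of 23 higher), each at adjusted p = 0.880 with an estimated correlation. In these 2 lists the respiratory chain subunit COX6B1 was at -0.21 and the hyaluronan receptor CD44 at 0.28. No member of these 4 lists passed, over all probe sets or adjusted over the list alone. The prostaglandin and leukotriene list, which holds the enzymes and receptors of the drug's own pathway, was not called (adjusted p = 0.704, median 0.03, 22 of 35 higher).

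IRF7 was the only probe set that limma called with nimesulide, and 890 had an unadjusted p under 0.05, where chance alone gives 819. With the replicate block the count was 37 probe sets, of which 8 rose and 29 fell. By their representative probe set 29 genes were called, and VEGFA and CADM1 only by another one. That number was not stable: in fits chosen after it was seen, it was 34, 2 and 1 without the arrays of letter A, B or C. Of those 29 genes, 16 belonged to the interferon list and fell and 3 belonged to the ATF4 list and rose (STC2, PSPH and SLC7A11). Among the 29, the 4 members of other lists are named after their values were seen: the death ligand TNFSF10 fell (-0.86, SE 0.19, adjusted p = 0.00271 with the block and 0.390 without), and the cornified envelope protein SPRR1B rose (0.87, SE 0.18, 0.0184 with the block and 0.30 without), as did the prostaglandin E2 receptor PTGER4 (0.47, SE 0.17, 0.0199 with the block and 0.906 without) and the protease inhibitor CSTA (0.44, SE 0.18, 0.0449 with the block and 0.906 without). Without the block, IRF7 did not pass when control B (adjusted p = 0.0655), control C (0.0766), nimesulide A (0.0848) or nimesulide C (0.103) was left out, and the count was 4 without control A and 2 without nimesulide B. Calls of the smaller shifts also ended when single arrays were left out of the fit without the block. The immediate early call ended without control C (adjusted p = 0.151) or nimesulide A (0.133). The oxidative phosphorylation call ended without control B (0.241) or nimesulide A (0.894). The basal keratinocyte call ended without control B (0.122), control C (0.133), nimesulide A (0.894), cisplatin A (0.0519) or cisplatin B (0.0516). In that order the basal keratinocyte median was 0.04, 0.07, 0.01, 0.05 and 0.05, so without either cisplatin array only the p moved. Leaving out a control or nimesulide array also unbalanced the letters. Within letters A, B and C the median change was 0.06, 0.08 and 0.06 for immediate early genes. It was -0.12, 0.00 and 0.00 for oxidative phosphorylation genes, and 0.13, 0.04 and 0.04 for basal keratinocyte genes. The oxidative phosphorylation call also ended with quantile normalization (adjusted p = 0.0826, median -0.03) or among genes above the median expression (0.0920, median -0.04). The basal keratinocyte call ended with the median of a gene's probe sets (0.0835, list median 0.05).

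**Figure D1:**
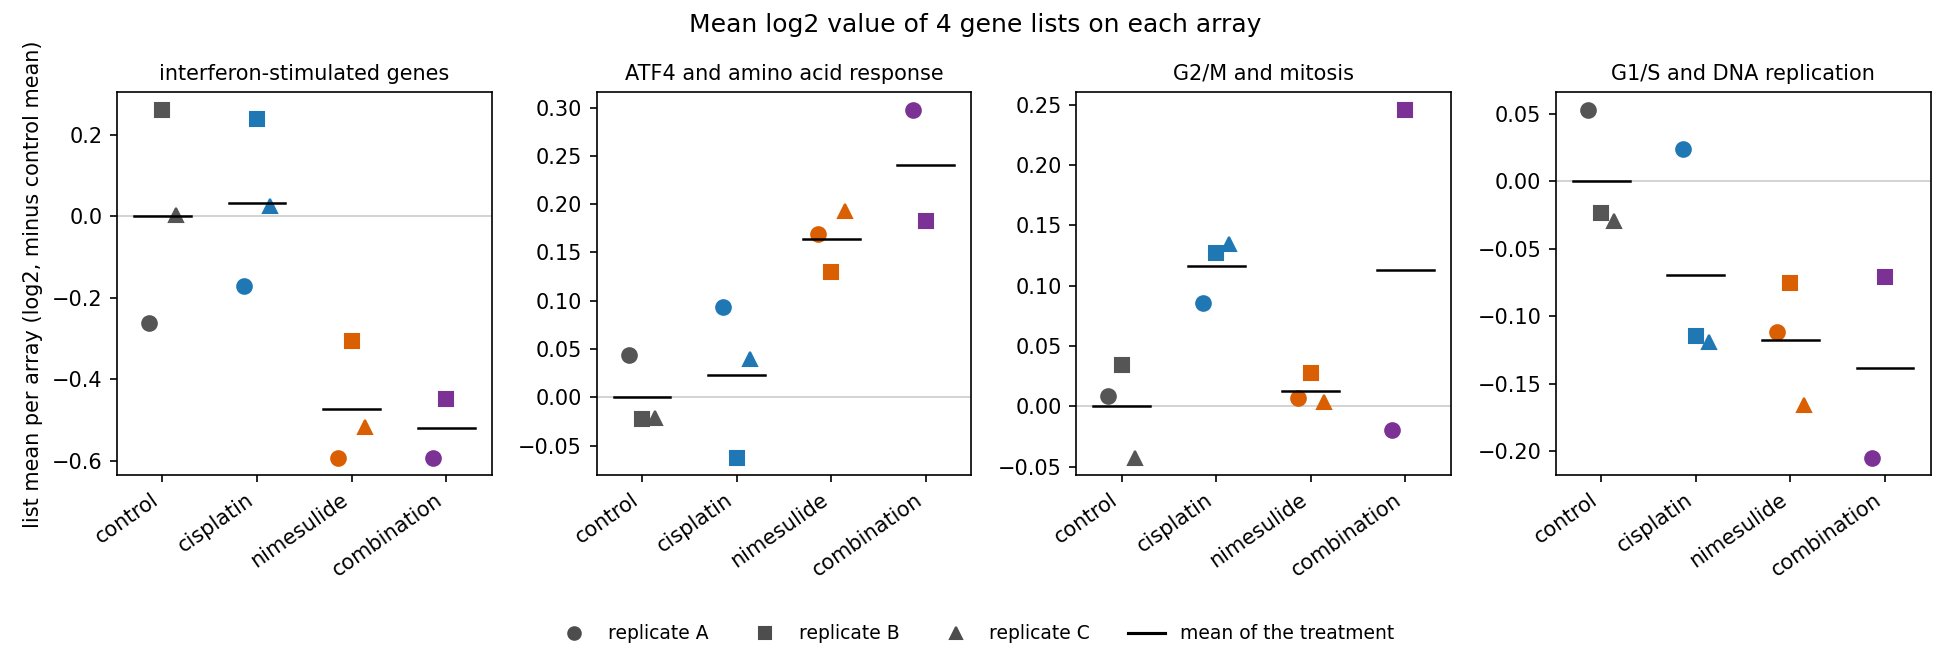
Mean log2 value of 4 gene lists on each of the 11 arrays, with the control mean subtracted; each point is an array, the marker shape gives the replicate letter and the line is the mean of the treatment. The 5 arrays with nimesulide lie at -0.31 or lower for the interferon-stimulated genes, and the 6 other arrays at -0.26 or higher.

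The combination against cisplatin asks what nimesulide adds to cisplatin, and it shares no array with nimesulide against control. The same 2 lists shifted most. Interferon-stimulated genes were lower by a median of -0.53 with all 33 members lower, and ATF4 response genes were higher by a median of 0.21 with 31 of 32 higher. Among their members IFI44L was at -1.74 (SE 0.32) and SLC7A11 at 0.66 (SE 0.11), with 2 combination and 3 cisplatin arrays.

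Both shifts were called (camera, adjusted p = 1.53e-32 for the interferon list and 2.37e-17 for the ATF4 list). Both calls were lost with an estimated correlation, at adjusted p = 0.181 with an estimated correlation for the interferon list and adjusted p = 0.170 with an estimated correlation for the ATF4 list. Adjusted over the list alone, 24 interferon members fell and 10 ATF4 members rose (27 and 15 with the block), while none passed over all probe sets. Genes of G1/S and DNA replication also fell as a group (adjusted p = 0.0239, median -0.08, 28 of 36 lower, adjusted p = 0.984 with an estimated correlation), with the flap endonuclease FEN1 at -0.32 (SE 0.12) and the polymerase clamp PCNA at -0.14 (SE 0.07), neither of which passed. This fall was seen in letter A only. Less the control mean, the G1/S list mean was -0.21 in combination A against 0.02 in cisplatin A. In letter B the combination stood higher, at -0.07 against -0.11.

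No probe set was called by limma for the combination against cisplatin, and 1162 had an unadjusted p under 0.05. The genes with the smallest p, none of which passed, were SLC7A11, ASNS (0.57, SE 0.10), the nucleoporin RANBP2 (0.44, SE 0.09), the endosomal protein RABEP1 (0.47, SE 0.10) and the drug efflux pump ABCG2 (0.35, SE 0.08) among those higher. Among those lower they were IFITM1 (-0.62, SE 0.09, adjusted p = 0.0746), IRF7 (-0.52, SE 0.08, adjusted p = 0.0779), APOL1 (-0.43, SE 0.08), IFI44L, and the transcriptional inhibitor ID3 (-0.52, SE 0.10), the last 3 at adjusted p = 0.204. With the replicate block 37 probe sets were called, 8 rising and 29 falling (37, 2 and 9 without letter A, B or C). By their representative probe set 28 genes were called, and VEGFA, EIF2AK2, OAS2 and PPP1R3D only by another one. The 28 included SLC7A11 (adjusted p = 0.0106), ASNS (0.0101), RANBP2 (0.0460), IFITM1 (0.00266), IRF7 (0.010), IFI44L (0.00266) and ID3 (0.0244). Of the 28 genes, 16 were interferon list members that fell and 3 were ATF4 list members that rose.

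With the block, 3 further lists were called: NF-kappaB and inflammatory cytokines lower (adjusted p = 0.00365, 0.233 without the block, 0.620 with the block and an estimated correlation), and NRF2 and oxidative stress genes and metallothioneins higher (both 0.0454, 0.212 and 0.460 without the block, both 0.638 with the block and an estimated correlation). The NF-kappaB list mean, less the control mean, was -0.07 in combination B against 0.11 in cisplatin B. In letter A it was -0.11 against -0.07. Without the block, 4 probe sets were called when control A was left out and 1 when nimesulide B was left out, 7 lists were called without combination B, and the G1/S call was lost without cisplatin A (adjusted p = 0.592) or combination A (0.899), and with the median of a gene's probe sets (0.0830).

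Across all 8549 genes, the log2 changes of nimesulide against control and of the combination against cisplatin correlated at r = 0.291 (rho = 0.129), and 52.9% of genes had the same sign. The value of r lay between 0.174 and 0.388 when single arrays were left out. By representative probe sets and with the replicate block, 22 genes fell in each of these contrasts and 16 of them were shared. Independent draws would share 0.0566, but that number cannot serve as a yardstick here. Both sets of calls came from 1 fit with a shared spread per probe set and shared letter effects. Most of the shared genes also belong to 1 list, so they were not independent. The shared genes were IFI27, IFI35, IFI44, IFI44L, IFI6, IFIT1, IFIT3, IFITM1, IRF7, ISG15, MX1, MX2, OAS1, RSAD2, SP110 and TNFSF10. Of 7 and 6 genes that rose, 1 was shared, SLC7A11. Another probe set of VEGFA, outside these numbers, also rose in both (adjusted p = 0.0199 and 0.0106 with the block), while its representative was at 0.06 and 0.13 and did not pass. For cisplatin against control and the combination against nimesulide, which also share no array, r was 0.102 (rho = 0.0788), and it reached -0.01 when combination B was left out.

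**Figure D2:**
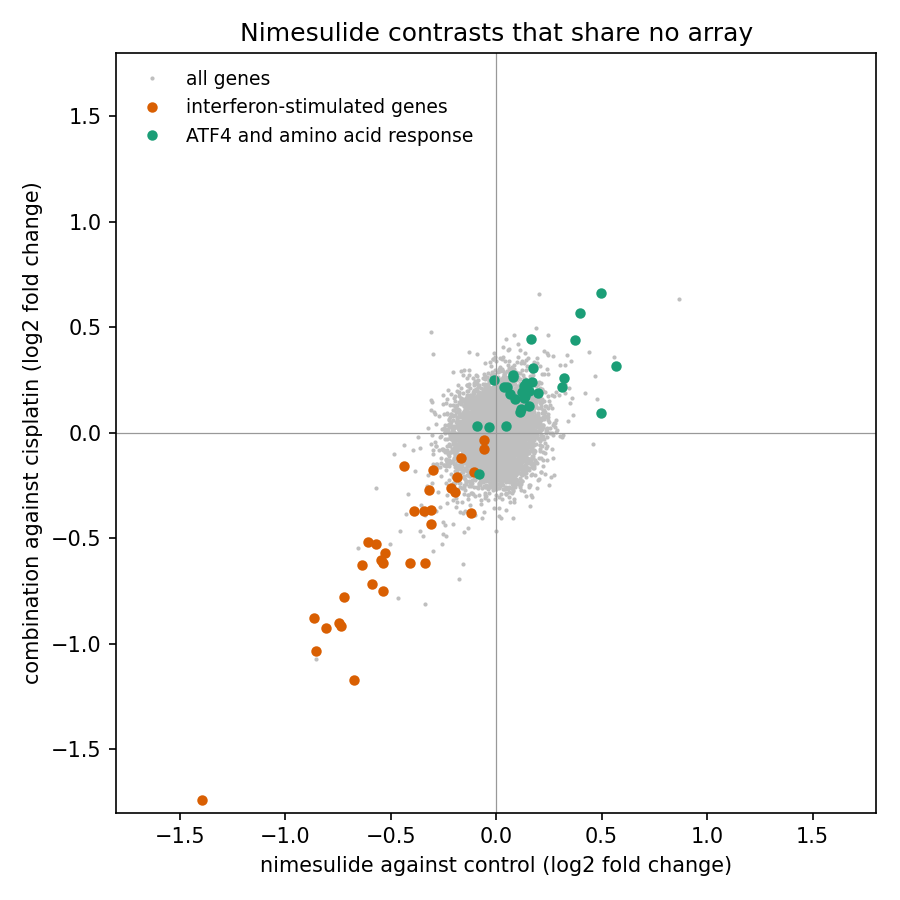
Log2 fold change of each gene for nimesulide against control (horizontal axis) and for the combination against cisplatin (vertical axis), which share no array; grey points are all 8549 genes and coloured points are members of the 2 named lists. Across all genes r was 0.291, and all 33 interferon-stimulated genes lie below 0 on both axes.

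**Figure D3:**
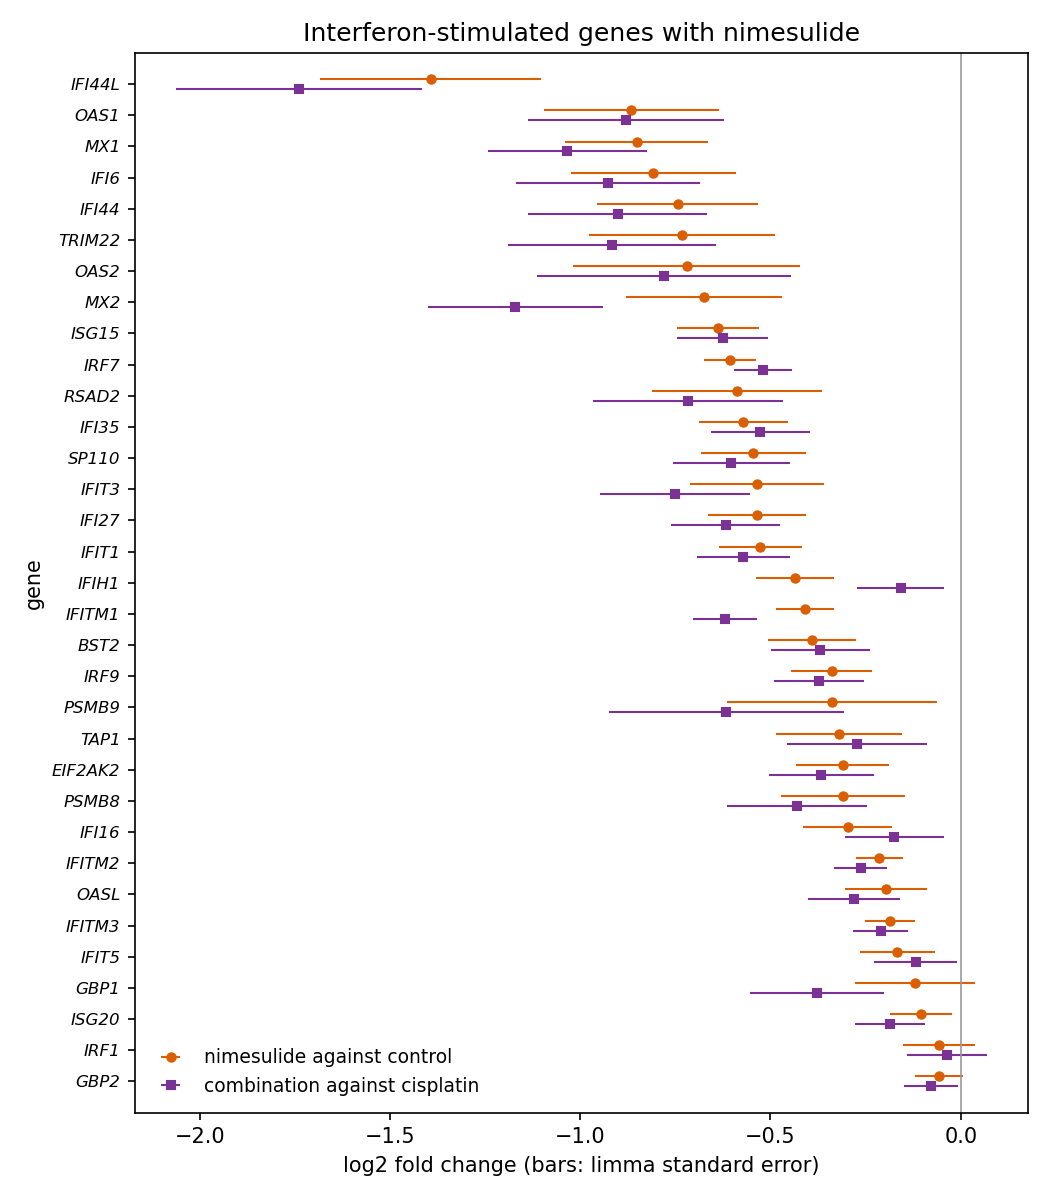
Log2 fold change of the 33 measured interferon-stimulated genes for nimesulide against control (circles) and for the combination against cisplatin (squares), with bars for the limma standard error. Every member is below 0 in both contrasts, from IFI44L at -1.39 and -1.74 to IRF1 at -0.06 and -0.04.

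The combination against control asks what both agents do together. Interferon-stimulated genes were at 7.40 ± 0.10 log2 units (SD, n = 2) against 7.92 ± 0.26 in controls (SD, n = 3), and ATF4 response genes at 8.31 ± 0.08 (SD, n = 2) against 8.07 ± 0.04 (SD, n = 3). Mitotic genes were higher by a median of 0.10 and replication genes lower by a median of -0.13. SLC7A11 was at 0.70 (SE 0.11) and IFI44L at -1.76 (SE 0.32), with 2 combination and 3 control arrays.

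The interferon list fell as a group (camera, adjusted p = 1.29e-23, 32 of 33 lower, adjusted p = 0.361 with an estimated correlation), with 20 members falling adjusted over the list alone (27 with the block) and none over all probe sets. The ATF4 list rose as a group (adjusted p = 3.80e-21, 30 of 32 higher, adjusted p = 0.101 with an estimated correlation), with 11 members rising adjusted over the list alone (19 with the block) and none over all probe sets. G2/M and mitosis genes rose (adjusted p = 5.13e-07, 28 of 36 higher) and G1/S and DNA replication genes fell (adjusted p = 3.11e-06, 31 of 36 lower), each at adjusted p = 0.564 with an estimated correlation. In these 2 lists the spindle protein DLGAP5 was at 0.37 (SE 0.10), the mitotic kinase NEK2 at 0.31 (SE 0.09), the G1 cyclin CCNE1 at -0.28 (SE 0.07) and the helicase subunit MCM2 at -0.27 (SE 0.08), none of which passed. With the block, 10 G1/S members fell adjusted over the list alone and 0 mitotic members rose, against 0 in each list without it. Basal keratinocyte and adhesion genes rose slightly (adjusted p = 0.00800, median 0.08, 17 of 23 higher, adjusted p = 0.637 with an estimated correlation), with the integrin ITGA6 at 0.26 (SE 0.08), although the basal keratin KRT5 was at -0.32 (SE 0.11); no member passed adjusted over the list alone without the block, and 4 rose with it. Immediate early genes rose as well (adjusted p = 0.00463, median 0.08, 20 of 28 higher, adjusted p = 0.564 with an estimated correlation), with the phosphatases DUSP1 at 0.16 and DUSP6 at 0.25, but not with the replicate block (adjusted p = 0.0513). Within letters A and B their median change was 0.07 and -0.01, with 19 and 14 of 28 members higher. Letter C, absent from the combination, stood lowest for this list among controls. Less the control mean, controls A, B and C stood at 0.03, 0.02 and -0.05.

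No probe set was called by limma for the combination against control, and 1295 had an unadjusted p under 0.05. The genes with the smallest p, none of which passed, were SLC7A11 (adjusted p = 0.0962), ASNS (0.56, SE 0.10), MTHFD2 (0.40, SE 0.08), the tubulin TUBB2A (0.42, SE 0.08) and the transfer RNA exporter XPOT (0.55, SE 0.11) on the higher side. On the lower side they were IRF7 (-0.53, SE 0.08, adjusted p = 0.0962), IFITM1 (-0.54, SE 0.09, adjusted p = 0.0962), IFI44L, the ion channel regulator TCAF1 (-0.35, SE 0.07) and NCKIPSD (-0.41, SE 0.08). With the replicate block 33 probe sets were called, 9 rising and 24 falling (45, 1 and 7 without letter A, B or C). By their representative probe set 22 genes were called, and VEGFA, TANK and KLK10 only by another one. The 22 included SLC7A11, IRF7 and IFITM1 (each at adjusted p = 0.00683), ASNS (0.0112), XPOT (0.0142) and IFI44L (0.00283), and 14 of the 22 genes were interferon list members that fell.

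The block also added cholesterol synthesis genes, higher (adjusted p = 0.0252, 0.162 without the block, 0.730 with the block and an estimated correlation), and NF-kappaB and inflammatory cytokine genes, lower (0.00994, 0.311 without the block, 0.433 with the block and an estimated correlation). Within letter B the median of the NF-kappaB list was -0.20 against control (25 of 37 members lower). Within letter A it was 0.02 (17 of 37 lower). Without combination A the medians were -0.11 for G1/S, 0.04 for immediate early and 0.02 for basal keratinocyte genes. Without combination B the median of mitotic genes was -0.01. Leaving out control C ended the call of immediate early genes (adjusted p = 0.0905, median 0.06). Keeping only genes above the median expression ended those of basal keratinocyte (0.117) and immediate early genes (0.115), while the medians did not shrink (0.11 in each list). Without nimesulide B 1 probe set was called.

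Cisplatin against control asks what the DNA-crosslinking agent alone does at this dose. Mitotic genes were higher, at 8.42 ± 0.03 log2 units against 8.30 ± 0.04 in controls (SD, n = 3 each), with 31 of 36 members higher. The mean of this list also differed by 0.27 between the 2 combination arrays, which is more than the difference between cisplatin and control. Replication genes were lower by a median of -0.10. The p53 target genes, which DNA damage commonly induces, were not called (adjusted p = 0.838, median 0.02, 7 of 13 measured members higher). The deposited table covered only these 13 of the 29 genes fixed for this list, so the test says nothing of the others.

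The G2/M and mitosis list rose as a group (camera, adjusted p = 1.12e-11, median 0.12, adjusted p = 0.80 with an estimated correlation). DLGAP5 was at 0.34 (SE 0.09), the spindle-associated hyaluronan receptor HMMR at 0.37 (SE 0.11), the checkpoint kinase TTK at 0.24 (SE 0.07) and the ubiquitin-conjugating enzyme UBE2C at 0.22 (SE 0.07). The G1/S and DNA replication list fell as a group (adjusted p = 0.0153, 25 of 36 lower, adjusted p = 0.80 with an estimated correlation), with the helicase subunits MCM4 at -0.25 (SE 0.07) and MCM2 at -0.18 (SE 0.07). Cholesterol synthesis genes (median 0.07, 12 of 18 higher) and immediate early genes (median 0.05, 18 of 28 higher) rose slightly, both at adjusted p = 0.0188 (0.80 with an estimated correlation), with the sterol oxidase MSMO1 at 0.33 (SE 0.10), the synthase HMGCS1 at -0.19 (SE 0.10), and the transcription factors FOSB at 0.15 (SE 0.08) and FOS at 0.17 (SE 0.10). No member of the 4 lists passed, over all probe sets or adjusted over the list alone, but with the block 5 mitotic genes rose adjusted over the list alone.

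No probe set was called by limma for cisplatin against control, with or without the replicate block, and 761 had an unadjusted p under 0.05 (1035 with the block), where chance alone gives 819. The genes with the smallest p, none of which passed (adjusted p = 0.903 to 0.968), included the RNA- and DNA-binding protein FUBP3 (0.41, SE 0.08), TUBB2A (0.31, SE 0.07), APOL1 (0.28, SE 0.07), PSPH (0.35, SE 0.09) and the decoy receptor TNFRSF11B (0.42, SE 0.11) among those higher. Among those lower were the matrix protein FBN2 (-0.31, SE 0.07), TMEM259 (-0.58, SE 0.14), the acetyltransferase KAT5 (-0.26, SE 0.06), the replication factor GINS4 (-0.32, SE 0.08) and the cadherin FAT2 (-0.30, SE 0.08). Calls ended for G1/S genes without control A (adjusted p = 0.326), cisplatin B (0.0565) or cisplatin C (0.387), for cholesterol genes without control B (0.478), cisplatin A (0.162) or cisplatin C (0.355), and for immediate early genes without control C (0.428), cisplatin A (0.227) or cisplatin B (0.0565). These fits held no block, so leaving out a control or cisplatin array also unbalanced the letters. Within letters A, B and C the median change was 0.05, 0.04 and 0.06 for cholesterol genes. It was -0.01, -0.08 and -0.05 for G1/S genes, and 0.05, -0.01 and 0.04 for immediate early genes. With the median of a gene's probe sets in place of the brightest, the cholesterol and immediate early lists were both at adjusted p = 0.216, and without cisplatin C 2 lists were called.

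The combination against nimesulide asks what cisplatin adds to nimesulide. Mitotic genes were higher by a median of 0.11 with 30 of 36 members higher, ATF4 response genes by a median of 0.10 with 24 of 32 higher, and cholesterol synthesis genes by a median of 0.08 with 16 of 18 higher. The interferon list was at a median of -0.05 (adjusted p = 0.922). All 3 shifts were called (camera, adjusted p = 4.3e-06, 0.000455 and 0.0240 in that order), and each was at adjusted p = 0.947 with an estimated correlation. The mitotic and cholesterol lists were higher in letter B only. Less the control mean, the mitotic list mean was 0.25 in combination B against 0.03 in nimesulide B. In letter A it was -0.02 against 0.01. The cholesterol list mean was 0.07 against -0.18 in letter B, and 0.03 against 0.07 in letter A. The ATF4 list mean was higher in both letters, at 0.30 against 0.17 in A and 0.18 against 0.13 in B. DLGAP5 (0.41, SE 0.10) rose adjusted over the list alone, though not over all probe sets, and the mitotic kinase AURKA was at 0.23 (SE 0.09). In the other lists the serine and glycine enzyme SHMT2 was at 0.19 (SE 0.08) and ACAT2, an early enzyme of sterol synthesis, at 0.24 (SE 0.11).

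No probe set was called by limma for the combination against nimesulide, with or without the block, and 1113 had an unadjusted p under 0.05 (1554 with the block). The genes with the smallest p, all at adjusted p = 0.672 to 0.707, were CAP2 (0.41), ZNF107 (0.39), TBPL1 (0.37), FERMT2 (0.34) and BTAF1 (0.35) on the higher side, and the nuclear receptor NR1I3 (-0.48), the growth regulator TSC2 (-0.41), TCAF1 (-0.32), NCKIPSD (-0.37) and SPART (-0.37) on the lower side, with standard errors of 0.07 to 0.09. With the replicate block the NF-kappaB list was also called, lower (adjusted p = 0.00147, 0.127 without the block, 0.866 with the block and an estimated correlation). Its list mean, less the control mean, was -0.07 in combination B against 0.15 in nimesulide B. In letter A it was -0.11 against -0.10. Without combination B the median was -0.01 for the mitotic list and 0.05 for the cholesterol list, and without combination A it was 0.02 for the ATF4 list. The cholesterol call was lost without nimesulide B (adjusted p = 0.620, median 0.03). It was also lost with quantile normalization (0.242, median 0.08) and among genes above the median expression (0.245, median 0.12), where the median did not shrink.

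Nimesulide against cisplatin tests directly whether the 2 single agents differ. Interferon-stimulated genes were lower with nimesulide by a median of -0.48, with all 33 members lower, and IRF7 fell by 0.59 log2 units relative to cisplatin (SE 0.07, n = 3 each, adjusted p = 0.00998). ATF4 response genes were higher by a median of 0.12, with 27 of 32 higher, and mitotic genes lower by a median of -0.08, with 31 of 36 lower. All 3 lists were called (camera, adjusted p = 3.66e-42, 5.37e-08 and 2.81e-08), with adjusted p = 0.194 with an estimated correlation for the interferon list, 0.510 for the ATF4 list and 0.861 for the mitotic list. Adjusted over the list alone, 24 interferon members fell (27 with the block), 5 ATF4 members rose (9 with the block) and 1 mitotic gene, DLGAP5 (-0.38, SE 0.09), fell. Cholesterol synthesis genes (adjusted p = 0.00130, median -0.06, 15 of 18 lower) and G1/S genes (adjusted p = 0.00673, median -0.05, 25 of 36 lower) also fell as groups, both at adjusted p = 0.861 with an estimated correlation, with the isomerase IDI1 at -0.28 (SE 0.09) and the cyclin CCNE2 at -0.29 (SE 0.10).

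IRF7 was the only probe set that limma called between the single agents, and 1079 had an unadjusted p under 0.05. With the replicate block 43 were called, 5 rising and 38 falling (53, 10 and 2 without letter A, B or C). By their representative probe set 33 genes were called, of which 16 were interferon list members that fell, and MAOA and OASL only by another one. The interferon list was the 1 list called with both the block and an estimated correlation (adjusted p = 0.0473 with an estimated correlation and the block). The count was 0 without cisplatin B, cisplatin C, nimesulide A or nimesulide C, 2 without control A and 3 without cisplatin A. The G1/S call was lost without cisplatin A (adjusted p = 0.674) or nimesulide C (0.203), and the cholesterol call without cisplatin C (0.0684) or nimesulide B (0.295).

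The interaction asks whether the combination departs from the sum of the single effects on the log2 scale. No list was called without the block. The ATF4 list was at a median of 0.07 (adjusted p = 0.270), the interferon list at -0.06 (0.439) and the mitotic list at -0.03 (0.844). The genes with the smallest p were TMEM259 (0.79, SE 0.20), TBPL1 (0.43, SE 0.11), the RNA helicase DDX39A (0.49, SE 0.14), FERMT2 (0.38, SE 0.11) and ZNF107 (0.40, SE 0.12) on the higher side. On the lower side they were TSC2 (-0.46, SE 0.11), ASGR1 (-0.40, SE 0.11), DSCR4 (-0.51, SE 0.13), FARP1 (-0.41, SE 0.11) and the bile acid transporter SLC10A1 (-0.32, SE 0.09). None of these 10 genes passed (all at adjusted p = 0.963). No probe set was called by limma, with or without the block, and 748 had an unadjusted p under 0.05 (1225 with the block). With the block the NF-kappaB list was called, lower than the sum of the single effects (adjusted p = 0.0178, 0.270 without the block, 0.931 with an estimated correlation and 0.946 with both), and without the block 4 lists were called when cisplatin A was left out, 3 without combination A, and 2 each without control B or combination B. Of these fits, those without control B and cisplatin A called the NF-kappaB list (adjusted p = 0.00292 and 0.0215).

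Genes of the p53 response and of cyclooxygenase, followed whatever their values, did not pass in any treatment. With cisplatin, nimesulide and the combination against control, in that order, the cell cycle inhibitor CDKN1A was at 0.09, 0.12 and 0.11, the p53 antagonist MDM2 at -0.11, -0.14 and -0.12, and the damage-induced gene GADD45A at 0.09, 0.22 and 0.19. PTGS2, which encodes cyclooxygenase-2, had a mean of 3.39 log2 units in controls, near the low end of the scale, and was at -0.12, -0.17 and -0.16. PTGS1, which encodes cyclooxygenase-1, was at -0.04, 0.10 and 0.09, and the mitotic survival gene BIRC5 at 0.14, -0.09 and 0.13. Signs hung on single arrays for GADD45A with cisplatin (-0.05 without control C, -0.00 without cisplatin B), for PTGS1 with cisplatin (0.05 without control C), nimesulide (-0.01 without control B) and the combination (-0.03 without control B), and for BIRC5 with the combination (-0.09 without combination B).

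The remaining lists were not called in any contrast without the block. Against control, with cisplatin, nimesulide and the combination in that order, DNA repair genes had medians of -0.01, -0.00 and -0.03, and platinum transport and detoxification genes -0.02, 0.03 and -0.05. Apoptosis regulators were at 0.02, -0.01 and 0.00, squamous differentiation genes at 0.01, 0.00 and -0.01, and NF-kappaB and inflammatory cytokine genes at -0.01, 0.00 and -0.08. Genes of NRF2 and oxidative stress were at -0.06, 0.02 and 0.02, aryl hydrocarbon receptor targets at 0.08, 0.04 and 0.01, metallothioneins at -0.05, 0.08 and -0.01, and genes of the heat shock response at -0.03, -0.03 and -0.05. Endoplasmic reticulum chaperones were at 0.01, -0.01 and -0.06, hypoxia and glycolysis genes at -0.02, -0.01 and -0.03, PPAR targets at -0.05, 0.01 and -0.02, TGF-beta targets at 0.02, -0.01 and 0.00, and EGFR ligands and receptors at -0.00, 0.08 and 0.05. Markers of other cell types were not called either, with fibroblast and mesenchymal genes at 0.03, 0.01 and -0.03 and leukocyte genes at -0.02, 0.02 and -0.05. The lists not called had adjusted p from 0.179 to 0.968 with cisplatin, from 0.216 to 0.872 with nimesulide and from 0.0686 to 0.925 with the combination. For p53 targets with the combination the test pointed up (adjusted p = 0.782) while the median was -0.03 and the mean 0.01.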

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

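Of the tests in this part, those of nimesulide itself, of cisplatin itself and of a joint fluctuation of the interferon or ATF4 genes, and the counts of probe sets over other splits of the arrays, were chosen only after the result was seen.

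NF-kappaB and inflammatory cytokine genes were not called for the interaction in the fit that gives the reported calls, and stand here because the list passed in some alternatives. The list was lower in the combination than the sum of the single effects with the replicate block (adjusted p = 0.0178, median -0.11). The combination stood apart mainly in letter B. There the list mean, less the control mean, was -0.07 in the combination and 0.14, 0.11 and 0.15 in control, cisplatin and nimesulide. In letter A these 4 arrays stood at -0.11, -0.11, -0.07 and -0.10. The other calls of this list with the block use the same combination arrays. Without the block the adjusted p was 0.270 (median -0.08, 27 of 37 members lower), it was 0.946 with the block and an estimated correlation, and no member passed adjusted over the list alone. With single arrays left out and no block, the list passed without control B (0.00292) or cisplatin A (0.0215), and in the 9 other fits the adjusted p was 0.0874 to 0.737.

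Interferon-stimulated genes were lower with nimesulide than in controls, by a median of -0.44. A single array cannot account for this, since the median nearest 0 among the 11 fits with an array left out was -0.35, nor can a shift of genes of like expression, since 0 of 10000 random lists of matched expression reached as far (their medians ran from -0.08 to 0.07). The shift was present within each letter, with a median of -0.34 at its nearest to 0. An additive difference between the letters was no test here, since it cancels where both treatments hold 1 array of each letter. Nimesulide itself predicts the shift on other arrays too, where the combination against cisplatin gave -0.53. As to a joint fluctuation of these genes between cultures, the list mean ranged over 0.52 among the controls, more than the difference of -0.47. That range followed the letters, however, so it does not measure a fluctuation that could produce this difference. Within a letter, arrays alike in nimesulide, which differ in cisplatin, were apart by at most 0.14, and nimesulide from control by at least 0.33. The within-letter values argue against a joint fluctuation as large as the shift, though 3 letters are too few to exclude it. Beside a joint fluctuation, a candidate explanation, found and tested on the same data, is that nimesulide lowers a standing interferon response of SCC9 cells. Whether the controls received the drug's solvent was not given in the sources used here.

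ATF4 and amino acid response genes were higher with nimesulide than in controls, by a median of 0.13. The median nearest 0 was 0.10 among the 11 fits with an array left out, and 0 of 10000 random lists of matched expression reached as far (-0.08 to 0.07). These values argue against a single array and a shift of genes of like expression. Within a letter the median nearest 0 was 0.13, so the rise was present in each letter. An additive difference between the letters cancels in this contrast and was not tested by it. The test of nimesulide itself on other arrays, the combination against cisplatin, gave 0.21. A joint fluctuation between cultures stays open, since the list mean ranged over 0.156 among the cisplatin arrays, near the difference of 0.16. Within a letter arrays alike in nimesulide differed by up to 0.128, where nimesulide and control differed by at least 0.125. The 0.128 lay between nimesulide A and combination A, which also differ in cisplatin, so it cannot measure fluctuation alone. A candidate explanation beside a joint fluctuation is that nimesulide induces this response. ATF4 messenger RNA itself was at 0.04, which does not decide this, since ATF4 protein was not measured. The solvent of the controls stays open here too.

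Mitotic genes were higher with cisplatin than in controls, by a median of 0.12, and by 0.09, 0.09 and 0.17 within letters A, B and C. The median nearest 0 among the fits with an array left out was 0.0761, and 0 of 10000 random lists of matched expression reached as far (-0.06 to 0.06), which argues against a single array and against a shift of genes of like expression. Cisplatin itself predicts a shift in the combination against nimesulide as well, where the median was 0.11, but this rested on 1 array, since it was -0.00843 without combination B. A joint fluctuation of cell cycle genes between cultures stays open, since the mean of this list ranged over 0.27 between the 2 combination arrays, more than the difference between cisplatin and control, although within each of the other 3 treatments it ranged over 0.08 or less, and within a letter arrays alike in cisplatin differed by up to 0.118, where cisplatin and control differed by at least 0.0771. The 0.118 lay between cisplatin B and combination B, which also differ in nimesulide, so it cannot measure fluctuation alone. Either cisplatin or a joint fluctuation could account for the pattern. Having 3 arrays per treatment with no overlap between cisplatin and control does not exclude chance differences between cultures.

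The 3 contrasts of 3 arrays against 3 allow 10 splits each, too few for a share under 0.05. For cisplatin against control 10 of the 10 splits called as many probe sets as the real one (0, highest other 0), and 7 called as many lists (4, highest other 7). For nimesulide against control 1 split, the real one, called as many probe sets (1, highest other 0), and 5 called as many lists (6, highest other 11). For nimesulide against cisplatin these numbers were 1 (1, highest other 0) and 5 (5, highest other 7). In that order the real splits called 0, 37 and 43 probe sets with the replicate block, and the highest other split 0 in each. The splits with the most lists parted only 1 of the 3 same-letter pairs, which points to a structure of the arrays by letter. Of the 10 splits in a contrast 4 part all 3 same-letter pairs, as the real one does, and among the others of these the highest number of lists was 2, 3 and 5. The real numbers of lists were above these for cisplatin and for nimesulide against control and equal for nimesulide against cisplatin, but over all 10 splits they did not stand out.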

How the results depend on the processing

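The fits with a replicate block that leave out a letter, and the replicate block with an estimated correlation, were chosen only after the results were seen. The direction of the 27 list calls and of most named genes was mostly kept (362 list values kept their call, 96 lost it and 1 reversed), but counts moved, and the cause was not tested unless stated. With arrays treated as paired by the replicate block, probe sets called rose from 1 to 37 (nimesulide against control), 0 to 33 (combination against control), 0 to 37 (combination against cisplatin) and 1 to 43 (nimesulide against cisplatin), and stayed at 0 for the other 3 contrasts. In that order, leaving letter A out of the block fit gave 34, 45, 37 and 53, leaving out B gave 2, 1, 2 and 10, and leaving out C gave 1, 7, 9 and 2; without A, 2 were called for the combination against nimesulide and 1 for the interaction. A spread moderated with a trend and robustly gave 2, 5, 3 and 9. A linear pseudocount gave 2 (nimesulide against control) and 4 (combination against control). For the combination against cisplatin, quantile normalization gave 2 and 1 probe set per gene 2. For nimesulide against cisplatin, array weights gave 4, the genes above the median expression 5, quantile normalization 3, median centring 9 and 1 probe set per gene 5. Nimesulide against control and against cisplatin gave 0 without probe sets of suffix _x_at or _s_at, which removes the IRF7 probe set itself, 0 when only the arrays compared were fitted, which leaves fewer arrays, and 0 at a fold of at least 2.

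Leaving out single arrays gave 0 to 4 probe sets for nimesulide against control, 0 to 1 for the combination against control, 0 to 4 for the combination against cisplatin and 0 to 3 for nimesulide against cisplatin. Lists called ranged from 2 to 5 for cisplatin, 4 to 7 for nimesulide and 3 to 8 for the combination against control, 2 to 7 for the combination against cisplatin, 2 to 4 against nimesulide, 4 to 6 for nimesulide against cisplatin and 0 to 4 for the interaction. With an estimated correlation 0 lists were called in every contrast, and with the replicate block as well 0, except 1 for nimesulide against cisplatin. With the block alone 6 lists were called for the combination against cisplatin and 1 for the interaction; with the median of a gene's probe sets 2 were called for cisplatin against control. Of the 297 list values with an array left out 32 lost the call and 1 reversed, mitotic genes in the combination against nimesulide (-0.00843 without combination B, and up to 0.25 over all arrays left out). Medians also changed sign, with the direction of the test kept, for mitotic genes in the combination against control (-0.01 without combination B) and cholesterol genes with cisplatin (-0.00 without control B). Within letters A, B and C the cholesterol median with cisplatin was 0.05, 0.04 and 0.06. Agreement between contrasts without shared arrays was 0.470 (nimesulide) and 0.171 (cisplatin) among genes above the median expression, and ran from 0.174 to 0.388 and from -0.0149 to 0.184 with single arrays left out.

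Named genes that turned were GADD45A with cisplatin (-0.0462 to 0.263, and -0.00104 without cisplatin B), PTGS1 with cisplatin (-0.16 to 0.0479), nimesulide (-0.0121 to 0.195) and the combination (-0.0279 to 0.180), and BIRC5 with the combination (-0.0897 to 0.352). Of the other values of named genes, 1067 kept their side of the threshold, 27 passed it and 4 lost it. Not run were the RNA quality comparison with its middle probe sets, agreement over called genes only (1 gene or none), and a fit of only the arrays compared for the interaction. With a combination array left out, the lone remaining one was assumed to vary like the other groups.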

Other observations

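The genes of this part, and the simulations with the letters kept, were chosen after the values were seen, and the calls come from the fit with the replicate block.

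With nimesulide against control, 6 of the 29 genes called by their representative probe set belonged to none of the lists. SREBF1, a transcription factor of lipid synthesis, fell by 0.57 log2 units (SE 0.19 without the block, adjusted p = 0.0249 with it and 0.906 without). IGFBP6, which binds insulin-like growth factor, fell by 0.42 (SE 0.08, 0.0199 and 0.266), and the placental alkaline phosphatase ALPP fell by 0.65 (SE 0.19, 0.0343 and 0.741). PSMB10 and PSME1, parts of the immunoproteasome that interferon induces, fell by 0.38 (SE 0.16, 0.0449 and 0.906) and by 0.33 (SE 0.09, 0.0461 and 0.657). TSC22D1, a transcriptional regulator, rose by 0.56 (SE 0.15, 0.0483 and 0.679).

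PTGER4, the EP4 receptor of prostaglandin E2, was higher than in controls with each treatment, at 0.52 with cisplatin (adjusted p = 0.0863 with the block), 0.47 with nimesulide (0.0199) and 0.69 with the combination (0.00320), where the fit without the block gave 0.79 (0.30). These 3 values share the control arrays, whose values of this gene had an SD of 0.35. Between the single agents, the basal keratin KRT14 was lower with nimesulide than with cisplatin (-0.87, SE 0.24, 0.0216 with the block and 0.480 without), and CYP1B1, a target of the aryl hydrocarbon receptor, was higher (0.42, SE 0.10, 0.0376 and 0.320).

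Contrasts that share the controls also resembled each other across genes, and shared arrays alone produce such a resemblance. The covariance of nimesulide and the combination against control was 0.00686, where simulations without an effect gave 0.00375 with independent arrays and 0.00304 with the letters kept. For cisplatin and the combination it was 0.00428 against 0.00374 and 0.00303, and for cisplatin and nimesulide 0.00331 against 0.00375 and 0.00305. For this last pair the observed value lay between the simulated ones, so shared controls alone gave about as much. For nimesulide against control and the combination against cisplatin, which share no array, it was 0.00355, where simulations with the letters kept gave -6.25e-06, so resemblance was also present without shared controls. The 3 control arrays cannot be divided into parts of 2 or more, so the part of the controls in the values above was simulated but not measured.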
